A study of Homo sapiens with 27 samples.

How the data were processed

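RNA was measured by paired-end sequencing with reads of 50 nucleotides, in 27 libraries from 3 human melanoma cell lines, A2058, A375 and SKMEL2. Per the labels' protocols, cells were infected with lentivirus carrying a non-silencing control hairpin or a hairpin against SIRT5, kept in puromycin at 1 µg/ml, and lysed in TRIzol 96 h after infection. The labels give the molecule as total RNA, and the selection of RNA for the libraries is not given in the sources used here. Each line has 3 control libraries (NT) and 3 libraries for each of 2 SIRT5 hairpins. The labels name the hairpins 546 and 547 while the deposited table names the knockdown columns KD1 and KD2. The sources used here do not say which is which, so the text speaks of the KD1 and KD2 arms only. Nothing states that the 3 libraries of a group came from separate cultures beyond separate wells. The p-values therefore measure the spread between wells, which may be technical.

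Per the submitters' processing notes, the authors used FastQC 0.11.9, MultiQC 1.9, Trimmomatic 0.39, STAR 2.7.3a, featureCounts of Subread 2.0.0 and DESeq2 1.28.1 with the GENCODE release 34 annotation of GRCh38. The roles and settings of these tools, and whether counting used the strand, are not given in the sources used here. The authors deposited FPKM values of 26004 genes in the 27 libraries. The authors also deposited 4 DESeq2 tables of knockdown against control, for each line and over all lines. In these tables the authors' base mean is a normalised signal averaged over libraries, the fold change is on the log2 scale, and each gene has a p-value and an adjusted p-value. Per the labels, 1 raw file of A375 control replicate 2 was truncated. Its library was kept, and the results without it are in the closing section.

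The FPKM columns are not counts, so the design written before the data were examined took limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5) as its test, with a variance trend, and Benjamini-Hochberg adjustment at 0.05. A fold change on this scale understates the change of genes with low FPKM. Genes entered a fit with an FPKM of at least 1 in at least 3 of its libraries. Each line was fitted alone with 3 groups, and the knockdown effect was the mean of the KD1 and KD2 arms minus the control. A gene was called with both hairpins when each arm passed with the same sign. A fit over all 27 libraries with 9 groups gave the mean effect over the lines and the F-test of a difference between lines. The KD1 and KD2 effects share the control libraries, so unchanged groups were simulated against those controls 20 times.

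The named genes follow a rule fixed before the data were examined. Per line these are the 6 rising and 6 falling protein-coding genes of largest change among those called with both hairpins, with every knockdown library on the same side of every control library and a mean FPKM of at least 2 in the higher arm. Over the 3 lines they are the 12 largest in each direction among genes called the same way in each line. Between hairpins they are the 3 largest in each direction per line, and between lines the 6 with the smallest adjusted p. From 34 gene lists, also fixed beforehand, up to 4 members of largest change are named. Some results on genes that these rules select are not reported here. Of the 34 lists, 32 had at least 3 measured members and were tested with camera at a preset correlation of 0.01, then with an estimated correlation and with fry, which asks only whether a list's genes move in 1 direction on balance.

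Sequencing depth, as reads assigned to the deposited genes, was recovered from the files. Products of the FPKM values and the authors' base means gave whole reads for 100% of the values above 0, within 0.05 of a whole number. Totals ran from 7.10 to 54.5 M reads per library, with a median of 31.2 M. The A375 libraries were the shallowest, at 7.10 to 23.9 M. These reads served for depth and for an added limma-voom alternative. No 2 libraries of a group agreed within sampling noise, with a mean chi-square per gene of 4.33 to 75.5, so none was counted as a duplicate. Gene positions, transcript sequences and 3' UTRs come from GENCODE release 44 on GRCh38, which matched 25905 of the gene identifiers (99.6%). The release differs from the authors' release 34.

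The fits were tested on simulated reads with 200 genes changed by 1.5, 2 or 4 times. In A2058, over 12346 genes, 98.5% of the changed genes were recovered, in A375, over 12324 genes, 91.5%, and in SKMEL2, over 13178 genes, 98.5%. At 1.5 times the recovered share was 95.5%, 74.6% and 95.5% in that order. False calls were 10, 12 and 10 genes. The simulation assumed a dispersion of 0.01. With nothing changed between hairpins, 1 gene was called in A2058, 1 in A375 and 0 in SKMEL2.

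Alternatives planned before the data were examined changed the pseudocount, the filter, the scaling, the variance model, the samples in the fit and the test of gene lists, and left out each library in turn. Those added afterwards were limma-voom on the recovered reads, each hairpin alone in each line, and removal of each library's trend with transcript length and GC content (splines with 5 degrees of freedom in each). Count models with size factors were not run on the recovered reads. Matches in 3' UTRs were sought as 7-mers in 9497 protein-coding genes with a 3' UTR of at least 50 nucleotides and expression in every line, adjusting for 3' UTR length and GC content. Arm-specific values were limited to 2 on the log2 scale in either direction. For the tests in other genes, 7-mers were chosen on alternate genes and tested on the rest. In simulated values a 7-mer lowered by a known amount came back at rank 1. The steps outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.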

Results

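Gene expression after SIRT5 knockdown was measured in 3 human melanoma cell lines, A2058, A375 and SKMEL2. SIRT5 is a sirtuin of mitochondria and cytosol that removes succinyl, malonyl and glutaryl groups from lysines. The series holds 27 RNA-seq libraries in 9 groups of 3. In each line a control arm (NT) expressed a non-silencing hairpin and the arms KD1 and KD2 each expressed a different SIRT5 hairpin, 96 h after infection. Library depth, taken as the recovered reads assigned to the deposited genes, was 29.3 to 54.5 M in A2058, 7.10 to 23.9 M in A375 and 20.2 to 40.5 M in SKMEL2. Expression is given as FPKM, the mean and SD of n = 3 libraries of an arm, or of n = 6 for both knockdown arms together. Changes are limma estimates on log2(FPKM + 0.5) with their SE, and adjusted p-values are limma's after Benjamini-Hochberg adjustment.

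The targeted gene was low in every knockdown library. SIRT5 (ENSG00000124523, GRCh38 chromosome 6, 13574227 to 13615158, plus strand) stood at an FPKM of 2.11 ± 0.282 in the A2058 controls, 0.178 ± 0.0420 in KD1 and 0.423 ± 0.0177 in KD2, so that KD1 kept 8.44% of control and KD2 20%. In A375 the SIRT5 values were 1.24 ± 0.109, 0.0484 ± 0.0327 and 0.154 ± 0.0527, or 3.89% and 12.4% of control. SKMEL2 had the highest SIRT5 level, 3.33 ± 0.377, with 0.234 ± 0.00764 in KD1, which is 7.01% of it, and 0.666 ± 0.0600 in KD2, which is 20%. The limma changes of SIRT5 were -1.72 ± 0.12 in A2058 (adjusted p = 4.2e-07), -1.54 ± 0.15 in A375 (adjusted p = 5.7e-05) and -2.05 ± 0.08 in SKMEL2 (adjusted p = 1.1e-07). More SIRT5 RNA was left in KD2 than in KD1 in A2058 (adjusted p = 0.012) and SKMEL2 (adjusted p = 0.00017). In A375, with 1 to 15 SIRT5 reads per knockdown library, this difference did not pass (adjusted p = 0.27). Among the other sirtuins, over the 3 lines, SIRT1 fell by 0.69 ± 0.11 (adjusted p = 6.3e-06) while SIRT4 and SIRT7 rose by 0.39 ± 0.11 and 0.30 ± 0.06.

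MITF, the transcription factor of the melanocyte lineage, fell with both hairpins in each line. Its FPKM was 35.2 ± 2.23 in the A2058 controls against 13.5 ± 0.662 in KD1 and 16.4 ± 1.87 in KD2. SKMEL2 went from a mean of 22.1 to 8.80 ± 1.24 and 10.4 ± 1.00, and A375, where MITF is low, from 3.54 ± 0.889 to 1.40 ± 0.386 and 1.88 ± 0.844. MYC, a driver of growth and ribosome production, fell in each line too, from 8.35 ± 0.182 to 4.47 ± 0.296 and 6.84 ± 0.811 in A2058, from 4.05 ± 0.127 to 1.90 ± 0.339 and 2.61 ± 0.598 in A375, and from 15.7 ± 0.485 to 8.76 ± 0.461 and 10.5 ± 0.0641 in SKMEL2. In the limma fits MITF changed by -1.22, -0.94 and -1.17 in A2058, A375 and SKMEL2, and MYC by -0.56, -0.75 and -0.69. MYC was lower in KD1 than in KD2 in A2058 (adjusted p = 9.7e-05) and in SKMEL2 (adjusted p = 0.00063). The 3' UTR of MYC carries the sequences described in the closing section for all 3 arms, and that of MITF none of them.

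**Figure D1:**
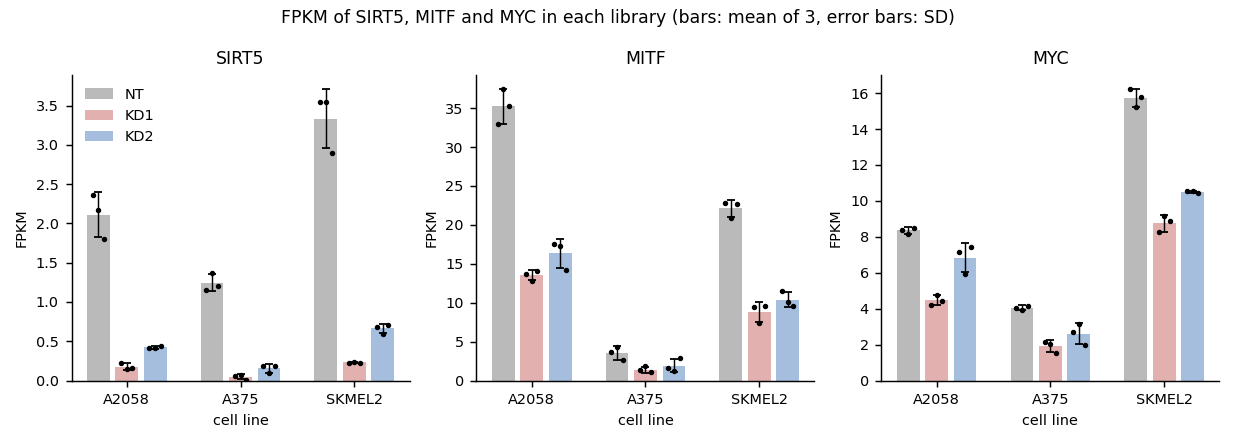
FPKM of SIRT5, MITF and MYC on the vertical axes in the 27 libraries by cell line and arm, with points for libraries, bars for means of 3 and error bars for SD. Every knockdown library lies below every control library of its line for SIRT5, where KD1 holds 3.89% to 8.44% of the control mean and KD2 12.4% in A375 and 20% in A2058 and SKMEL2.

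Which genes answered to SIRT5 knockdown in all 3 lines was the broadest question of the design. SERPIND1, which encodes the thrombin inhibitor heparin cofactor II, rose by 2.62 ± 0.07 over the lines, the largest increase of the named genes, from an FPKM of 1.82 ± 0.252 to 25.6 ± 3.69 in A2058. The tight junction gene CLDN4 rose by 2.30 ± 0.07, the cytochrome c oxidase subunit gene COX7C by 2.14 ± 0.05, and DUSP5, a nuclear phosphatase of ERK, by 2.08 ± 0.05. COX7C varied little among libraries, at 25.9 ± 1.39 in the A2058 controls and 116 ± 5.66 in the 6 knockdown libraries. The other named increases were PBXIP1 (2.03), the receptor gene MRGPRX4 (2.03), the metalloproteinase gene MMP15 (1.84), the mitochondrial ribosomal gene MRPS6 (1.81), TMEM158 (1.80), the cap-binding gene EIF4E2 (1.78) and the vitamin B12 carrier TCN1 (1.75). Of these 11 genes, 5 carry in their 3' UTR the 7-mer GAAGAGC, which went with low expression in the control arm (closing section). They are CLDN4, COX7C, MMP15, MRPS6 and EIF4E2.

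Of the 12 decreases named over the lines, 6 were in genes induced by interferon. IFIT1 fell by 2.66 ± 0.17, IFIT2 by 1.90 ± 0.10, IFIT3 by 1.88 ± 0.15, OASL by 1.64 ± 0.10, IFI44 by 1.64 ± 0.16 and OAS3 by 1.54 ± 0.12. The ethanolamine kinase gene ETNK2 fell by 1.92 ± 0.06, the cationic amino acid transporter SLC7A1 by 1.56 ± 0.05, the proteoglycan gene SDC1 by 1.55 ± 0.07, MFSD3 by 1.54 ± 0.06, PA2G4, a growth-regulating RNA-binding protein, by 1.52 ± 0.04 and the receptor gene GPR3 by 1.52 ± 0.06. The adjusted p-values of these 23 genes lay between 1.5e-18 (COX7C) and 1.1e-08 (IFI44). The 3' UTRs of ETNK2, PA2G4 and GPR3 carry the 7-mers of both knockdown arms. That of OAS3 carries the 7-mer of KD1 and also that of the control arm, and that of SLC7A1 the 7-mer of KD2. These genes too were among those used to choose the sequences.

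**Figure D2:**
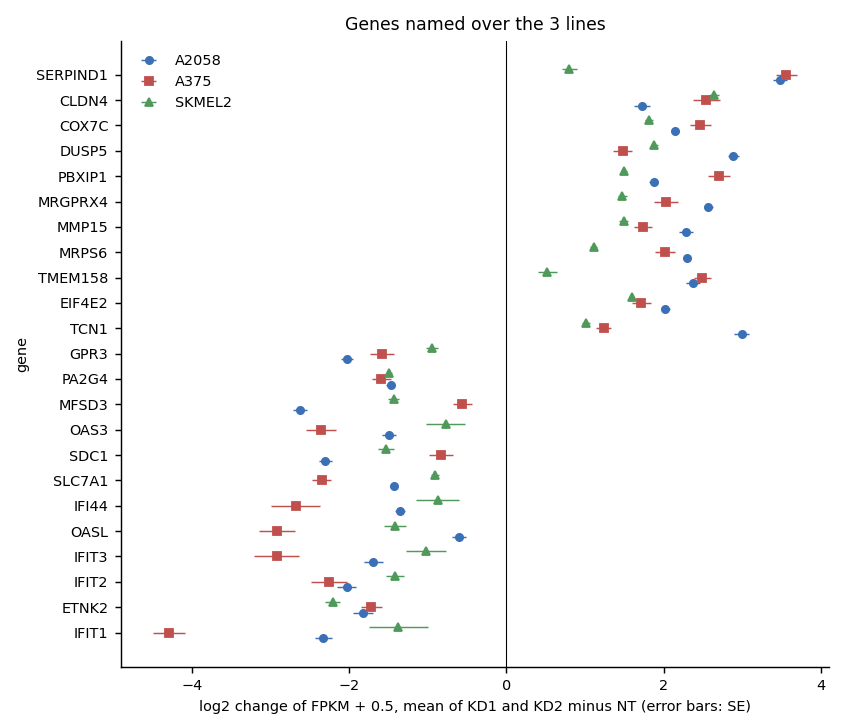
Changes of the 23 genes named over the 3 lines, on the horizontal axis as log2 change of FPKM + 0.5 in the mean of both knockdown arms against control with SE, each symbol being a line. IFIT1 in A375, at -4.29, is the largest change shown, and SERPIND1 rose less in SKMEL2 (0.80) than in A2058 (3.49) or A375 (3.56).

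Among the gene lists, the interferon response was lower as a whole. All 28 measured members fell over the 3 lines, 28 also when adjusted over the list alone, with a median of -1.14 (camera adjusted p = 1.2e-10, and adjusted p = 0.29 with an estimated correlation). The G2/M cell cycle list fell with 24 of 26 members and 2 not passed, median -0.66 (camera adjusted p = 7.3e-08, adjusted p = 0.29 with an estimated correlation). This fall depended on the hairpin. KD2 lay above KD1 by a median of 0.88 over the lines (camera adjusted p = 2.7e-10, adjusted p = 0.36 with an estimated correlation). MKI67 changed by -1.09 ± 0.08, TOP2A by -1.08 ± 0.16 and CENPE by -0.96 ± 0.11. Of the G1/S list 19 members fell, 2 rose and 5 did not pass, median -0.37, with RRM2 at -0.95 and TYMS at -0.79 (camera adjusted p = 6.6e-05, adjusted p = 0.32 with an estimated correlation). Adjusted over the list alone, 24 G2/M genes and 20 G1/S genes fell. Neither fall held in every line: in SKMEL2 the G2/M list was not called, with 11 members falling and 4 rising (median -0.12, camera adjusted p = 0.25), and in A2058 the G1/S list was not, with 9 falling and 9 rising (median -0.04, camera adjusted p = 0.89). In SKMEL2 the G2/M median lay below control in KD1 and above it in KD2, so its value there averages opposite directions.

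Pigment cell genes were lower over the lines. Of 23 members of the pigmentation list 18 fell, 1 rose and 4 did not pass, the same counts adjusted over the list alone, with DCT at -1.33 ± 0.07, OCA2 at -1.02 ± 0.08 and TYRP1 at -0.94 ± 0.05, all enzymes or transporters of melanosomes (camera adjusted p = 2.6e-06, adjusted p = 0.24 with an estimated correlation). Genes of the ATF4 stress response were lower in 22 of 28 cases, higher in 5 and not passed in 1, also adjusted over the list alone. Their median was -0.50, with the amino acid transporter SLC7A5 at -1.25 ± 0.05, ATF3 at -1.10 ± 0.06 and the serine synthesis enzyme PSAT1 at -1.06 ± 0.05 (camera adjusted p = 2.5e-05, adjusted p = 0.29 with an estimated correlation). The ATF4 list did not fall in SKMEL2, where 14 members rose and 9 fell, with a median of 0.13 (camera adjusted p = 0.51). MYC targets fell in 24 of 36 cases, rose in 6 and did not pass in 6, median -0.29, led by PA2G4 and by NOLC1 at -1.33 ± 0.04 (camera adjusted p = 0.00056, adjusted p = 0.24 with an estimated correlation); 25 fell adjusted over the list alone. The NRF2 list had 18 decreases, 3 increases and 2 not passed of 23, also adjusted over the list alone. NQO1 was at -0.86 ± 0.05 and GCLM at -0.58 ± 0.05, while HMOX1 went the other way at 1.11 ± 0.07 (camera adjusted p = 0.0032, adjusted p = 0.29 with an estimated correlation). Fatty acid synthesis genes fell in 8 of 16 cases, rose in 4 and did not pass in 4, also adjusted over the list alone, with the desaturase SCD at -1.19 ± 0.05 and FASN at -0.61 ± 0.05 (camera adjusted p = 0.040, adjusted p = 0.24 with an estimated correlation).

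Lysosomal genes were higher. Of 26 members 18 rose, 1 fell and 7 did not pass, with the hydrolase gene NEU1 at 0.76 ± 0.06 and the proton pump gene ATP6V0D1 at 0.66 ± 0.06 (camera adjusted p = 6.5e-05, adjusted p = 0.33 with an estimated correlation); 19 rose adjusted over the list alone. Apoptosis regulators rose in 16 of 25 cases, fell in 4 and did not pass in 5, also adjusted over the list alone. BIRC3, an inhibitor of cell death, was at 1.24 ± 0.14, while the pro-death PMAIP1 and the anti-death BCL2L1 fell to -0.88 ± 0.08 and -0.81 ± 0.07, so the list holds genes of either action (camera adjusted p = 0.038, adjusted p = 0.24 with an estimated correlation). Targets of p53 rose in 11 of 24 cases, fell in 3 and did not pass in 10, also adjusted over the list alone, with BTG2 at 1.07 ± 0.07 and AEN at 0.87 ± 0.05 (camera adjusted p = 0.040, adjusted p = 0.29 with an estimated correlation). Histone genes rose in 17 of 35 cases, fell in 2 and did not pass in 16, with 16 rising adjusted over the list alone and H1-2 at 1.29 ± 0.08 (camera adjusted p = 0.018, adjusted p = 0.61 with an estimated correlation). The rise came mainly with KD2, which was above KD1 by a median of 0.82 over the lines (camera adjusted p = 4.0e-06, adjusted p = 0.36 with an estimated correlation), and in A2058 the histone median was -0.60 in KD1 and 1.03 in KD2. Reads of near-identical histone genes can be split between copies, so single members are uncertain. MHC class I genes rose in 9 of 14 cases, fell in 2 and did not pass in 3, also adjusted over the list alone, with HLA-B at 0.92 ± 0.07, HLA-C at 0.79 ± 0.06 and the peptide transporter TAP1 at -0.72 ± 0.07 (camera adjusted p = 0.034, adjusted p = 0.61 with an estimated correlation).

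In total 10354 of 16162 genes changed over the 3 lines, 5177 in each direction, and 301 of them by at least 2 times. The filter of this fit counts all 27 libraries together, so genes that did not pass in every line are included. Called the same way in each line's own fit were 2250 of 10581 genes tested in all, 1134 rising and 1116 falling, where independent lists of these sizes would share 330 and 290. The effects correlated across genes between lines at r = 0.636 for A2058 and SKMEL2, 0.426 for A2058 and A375 and 0.415 for A375 and SKMEL2, genes not being independent replicates. With each hairpin tested alone, 710 genes kept their direction in all 6 contrasts, 437 rising and 273 falling. Of the 32 lists 13 passed with camera, a number that 6 of 100 regroupings of the libraries within lines reached, and 0 passed with an estimated correlation. Of these 13, only the interferon and lysosome lists were called with camera in the single fits of all 3 lines. The pigmentation list was called in A2058 and SKMEL2, the G2/M and ATF4 lists in A2058 and A375, and the G1/S, MYC target and MHC class I lists in A375 and SKMEL2. Called in 1 line were the NRF2 and apoptosis lists (A2058), the p53 and histone lists (A375) and fatty acid synthesis (SKMEL2). These calls depended on scaling in part. In the fit over all libraries quantile normalization added calls of falling MYC targets in A2058 (camera adjusted p = 0.0097), NRF2 genes in A375 (0.00068) and fatty acid synthesis in A2058 and A375 (0.026 and 0.018). It ended that of the apoptosis list in A2058, whose median went from 0.32 to 0.34 (adjusted p = 0.061). Once each library's trend with transcript length and GC content was removed, histones lost their call in A375 (median 0.51 to 0.23, adjusted p = 0.31) and over the lines (0.30 to 0.20, adjusted p = 0.16), and fatty acid synthesis over the lines (-0.17 to -0.12, adjusted p = 0.16). The p53 list missed the threshold over the lines under quantile normalization with a similar median (0.17 to 0.14, adjusted p = 0.061).

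In A2058 the knockdown arms gained transcripts of the heat shock gene HSPA6 (FPKM 1.87 ± 0.514 to 30.8 ± 26.9), TCN1 (3.23 ± 0.451 to 35.8 ± 23.3), DUSP5 (4.40 ± 0.342 to 36.1 ± 6.07), the myosin gene MYH15 (0.163 ± 0.0152 to 4.52 ± 1.89) and NT5E, the ectoenzyme CD73 (11.1 ± 0.344 to 72.9 ± 27.5), besides SERPIND1. HSPA6 shares much of its sequence with a paralog, so its level is uncertain. The named decreases were the carbonic anhydrase CA9 (3.98 ± 1.40 to 0.194 ± 0.125), MFSD3 (27.3 ± 1.56 to 4.99 ± 3.41), LGALS12, IFIT1, SDC1 (20.9 ± 0.929 to 4.16 ± 1.82) and the matrix gene EFEMP1 (8.59 ± 0.0983 to 1.37 ± 0.187). The limma changes of these 12 genes ran from 3.49 ± 0.09 for SERPIND1 to -2.66 ± 0.21 for CA9, with adjusted p-values of at most 1.2e-06 (CA9). Within this line the G2/M list fell with 25 of 26 members (camera adjusted p = 1.2e-10), the interferon list with 20 of 24 and 1 rising (camera adjusted p = 3.1e-06), and cholesterol synthesis with 17 of 24 and 1 rising (camera adjusted p = 0.00048). Their adjusted p-values with an estimated correlation were 0.35, 0.40 and 0.35.

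The A2058 fit called 8873 of 12797 genes, 4429 up and 4444 down, 895 of them with at least 2 times the change. Both hairpins moved 4736 genes the same way, 2476 up and 2260 down, against 1634 and 1517 for independent lists, and 1988 genes in opposite directions. The effects of KD1 and KD2 correlated at r = 0.413, where unchanged groups against the same controls gave 0.497. Their covariance was 0.171 against a simulated 0.00786, a difference of 0.163. In simulations without any effect 0 genes were called with both hairpins in limma. These simulations hold only the noise between libraries. An effect of the control hairpin itself would enter both contrasts and is not in them. With 3 control libraries per line the controls cannot be halved, so part or all of each such excess may come from the shared controls.

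In A375 the named increases were SERPIND1 (FPKM 2.86 ± 0.249 to 53.6 ± 9.30 in KD1 and 29.1 ± 4.72 in KD2), the complement gene C3 (2.74 ± 0.318 to 51.9 ± 48.8), the protease inhibitor gene PI3 (listed at 0 in the controls and at 9.24 ± 2.57 in KD1 and 1.14 ± 0.412 in KD2), the water channel AQP3 (4.44 ± 0.244 to 38.3 ± 20.8), PBXIP1 (16.4 ± 1.28 to 113 ± 30.5) and CLDN4. Interferon genes made up most of the named decreases. IFIT1 went from 19.3 ± 7.70 to 0.471 ± 0.0937, which is 41.0 times lower, MX1 from 16.4 ± 6.66 to 1.14 ± 0.470, OAS2 from 23.9 ± 8.88 to 2.09 ± 0.943, IFIT3 from 23.1 ± 9.11 to 2.57 ± 0.852 and OASL from 5.69 ± 2.22 to 0.322 ± 0.269, and CA9 was again among them, from 7.83 ± 0.0798 to 0.713 ± 0.373 in KD1 and 0.288 ± 0.0324 in KD2. All 12 changes had adjusted p-values of at most 5.9e-05 (IFIT3). The interferon list fell with 24 of 25 members, 0 rising, and a median of -2.18 (camera adjusted p = 1.2e-14). The G1/S list fell with 21 of 26 members, the G2/M list with 23 of 25, and the ATF4 list with 17 of 25 and 1 rising (camera adjusted p = 1.2e-08, 2.2e-08 and 2.6e-08). Cytosolic ribosome genes rose in 59 of 75 cases and nuclear genes of oxidative phosphorylation in 32 of 66 (camera adjusted p = 4.5e-10 and 1.6e-05). With an estimated correlation the adjusted p was 0.32 for the interferon and both cell cycle lists and for the ATF4 list, and 0.62 for the ribosome and oxidative phosphorylation lists. Both lists went the other way elsewhere: ribosome genes fell in A2058 (47 of 75, 5 rising, median -0.14, camera adjusted p = 0.00023) and SKMEL2 (45 of 75, 2 rising, median -0.14, camera adjusted p = 0.00042), and oxidative phosphorylation genes in SKMEL2 (36 of 66, 11 rising, median -0.13, camera adjusted p = 0.0043), with adjusted p = 0.75, 0.61 and 0.61 with an estimated correlation. In A2058 the ribosome list lay below control in KD1 and above it in KD2, so its fall there is an average of opposite directions. Over the lines it was higher in KD2 than in KD1 by a median of 0.68 (camera adjusted p = 8.0e-22, adjusted p = 0.36 with an estimated correlation). Under quantile normalization the oxidative phosphorylation median in A375 was 0.16 in place of 0.38, and the ribosome median there dropped by more (other observations). The pigmentation list was not called in this line.

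The A375 fit called 6054 of 12629 genes, 3314 up and 2740 down, 1111 of them at 2 times or more. Both hairpins moved 2807 the same way, 1623 up and 1184 down, against 758 and 523 for independent lists, and 423 in opposite directions. The correlation of their effects was 0.534 with a simulated 0.499, and the covariance 0.263 with a simulated 0.0228, a difference of 0.241. The count called with both hairpins was 1665 without control replicate 2 and 1830 without control replicate 1, and 4143 without KD2 replicate 3.

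In SKMEL2 the named increases were CLDN4 (FPKM 1.18 ± 0.111 to 11.3 ± 5.95), the trophoblast gene PLAC1 (0.479 ± 0.182 to 4.88 ± 2.32), VCX2, DUSP5 (20.5 ± 1.12 to 82.4 ± 32.2), the laminin gene LAMB3 (6.30 ± 0.571 to 24.2 ± 2.09) and the transcriptional repressor E2F7 (5.39 ± 0.530 to 22.1 ± 8.74). VCX2 has near-identical family members and its value is uncertain. ETNK2 (4.44 ± 0.309 to 0.582 ± 0.187), the transporter SLCO4A1 (10.4 ± 0.253 to 2.40 ± 0.539), the carbonic anhydrase CA14 (9.75 ± 0.201 to 2.33 ± 0.185), OAS2, the adhesion gene CDH1 (3.17 ± 0.470 to 0.641 ± 0.325) and the pigment enzyme DCT (31.0 ± 2.82 to 9.20 ± 2.01) fell. OAS2 changed by -1.84 ± 0.56 (adjusted p = 0.015), and by -0.87 without control replicate 3, the highest control, the FPKM of the 3 controls being 6.47 ± 8.26 with 1.87 and 1.53 in the other 2. The other 11 changes had adjusted p-values of at most 8.0e-06 (CDH1). Here the pigmentation list fell with 19 of 21 members and 1 rising, median -0.88 (camera adjusted p = 1.4e-05, adjusted p = 0.58 with an estimated correlation). The interferon list fell with 14 of 22, median -0.69 (camera adjusted p = 0.0043, adjusted p = 0.61 with an estimated correlation), and the median was -0.32 without control replicate 3.

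The SKMEL2 fit called 9070 of 13899 genes, 4572 up and 4498 down, but only 481 with at least 2 times the change. Both hairpins moved 4639 the same way, 2436 up and 2203 down, against 1554 and 1419 for independent lists, and 1722 in opposite directions. The correlation was 0.406 with a simulated 0.504, and the covariance 0.109 with a simulated 0.00625, a difference of 0.103.

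**Figure D3:**
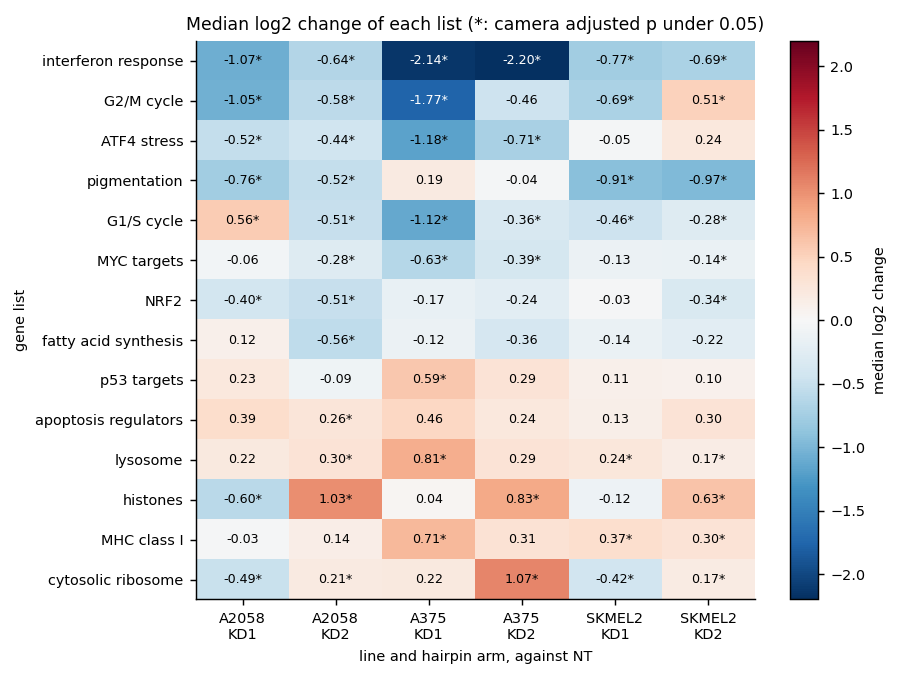
Median log2 change of 13 gene lists called over the 3 lines and of the cytosolic ribosome list (vertical axis) for each line and hairpin arm against control (horizontal axis), with an asterisk at a camera adjusted p under 0.05. The interferon list is low in all 6 contrasts, at -0.64 in A2058 KD2 and -2.14 in A375 KD1, while the G2/M list is at -0.69 in KD1 and 0.51 in KD2 of SKMEL2.

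The 2 hairpins were then compared with each other. In A2058 the peptide hormone gene UTS2 and the methyltransferase NNMT fell in KD1 and rose in KD2, NNMT from an FPKM of 16.9 ± 0.986 to 1.53 ± 0.171 and 45.7 ± 1.36, and RASD1 did likewise. The cell cycle inhibitor CDKN1A went the other way, from 43.9 ± 1.36 to 158 ± 6.57 in KD1 and 13.6 ± 2.02 in KD2, as did SPRR2D and the cytokine IL1A. In A375 SEMA6B, HAX1 and DAG1 were lower in KD1, DAG1 at 7.45 ± 0.259 against 83.4 ± 13.6 in KD2, while SAT1, an enzyme of polyamine breakdown, was at 235 ± 15.5 in KD1 and 10.2 ± 1.42 in KD2. LCE1F and LCE1D, skin barrier genes of a family with close copies, were higher in KD1. SKMEL2 had the same low SEMA6B and DAG1 in KD1, with DAG1 at 6.60 ± 0.328 against 51.9 ± 3.08, along with LZTS1, and high CD300LB, NRARP and MUC20 in KD1. The KD2 minus KD1 differences of these genes ran from -5.54 ± 0.30 for LCE1F in A375 to 4.57 ± 0.20 for UTS2 in A2058, with adjusted p-values of at most 2.0e-05 (LCE1D).

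**Figure D4:**
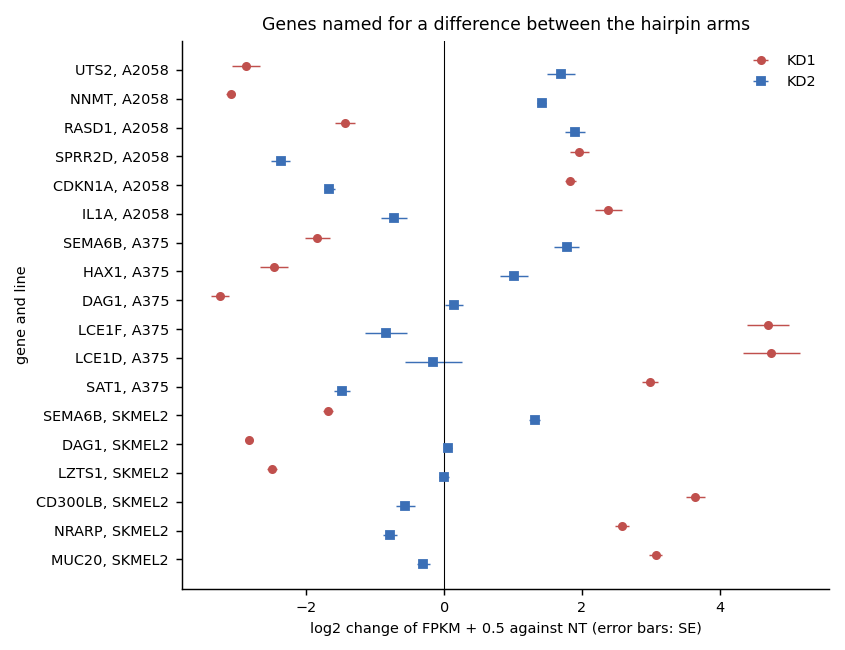
Changes in KD1 and KD2 of the genes named for a difference between the hairpin arms, on the horizontal axis as log2 change of FPKM + 0.5 against control with SE. NNMT in A2058 is at -3.10 in KD1 and 1.41 in KD2, and DAG1 in SKMEL2 at -2.83 and 0.06.

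Cytosolic ribosome genes separated the hairpins in every line. They were higher in KD2 than in KD1 for 68 of 75 members in A2058 and lower for 4, for 67 in A375 and for 69 in SKMEL2 with 1 lower (camera adjusted p = 1.7e-18, 1.1e-19 and 1.7e-16, and adjusted p = 0.59, 0.56 and 0.83 with an estimated correlation). Against control the A2058 list median was -0.49 in KD1 and 0.21 in KD2. The G2/M list was higher in KD2 too, for 17 of 26 members in A2058 with 6 lower, 21 of 25 in A375 and 26 of 26 in SKMEL2 (camera adjusted p = 0.0096, 4.0e-12 and 7.7e-11, and adjusted p = 0.78, 0.28 and 0.83 with an estimated correlation). For G1/S genes the median KD2 minus KD1 difference was -0.97 in A2058 and 0.99 in A375. Over the lines the G1/S list was not called between the hairpins (median 0.06, camera adjusted p = 0.57). Genes called between the hairpins numbered 9249 in A2058 (4041 higher in KD2 and 5208 lower), 4811 in A375 (2135 and 2676) and 9522 in SKMEL2 (4623 and 4899). The split by direction depended on scaling: under quantile normalization 4590 were higher and 4565 lower in A2058, and 2701 and 2446 in A375. Without such scaling, 962 were higher and 1345 lower in KD2 in all 3 lines, against 178 and 365 for independent lists.

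The effect of the knockdown on some genes depended on the line. The protease inhibitor gene A2M rose by 2.41 in A375, from an FPKM of 3.17 ± 0.270 to 19.4 ± 4.80, and changed by -0.82 in A2058 and -0.25 in SKMEL2. TIMP1, an inhibitor of metalloproteinases, fell in A375 from 1932 ± 123 to 609 ± 164 and rose in A2058 from 144 ± 6.61 to 320 ± 127. CD55 and GPAT3 fell in A375 (-1.53 and -0.64) and rose in A2058 (0.77 and 1.23) and SKMEL2 (0.63 and 0.71). The endothelin receptor gene EDNRB rose in A375 (2.11) and A2058 (0.99), with 0.00 in SKMEL2, and TGFBR2 rose by 1.41 in A375 and 0.42 in A2058, with -0.13 in SKMEL2. The F-test of a difference between lines called 9881 of 16162 genes, with adjusted p-values from 4.5e-15 (A2M) to 6.1e-12 (TGFBR2) for these 6. Its fit gives each gene 1 variance shared by the lines. A375 libraries varied more within arms, so these p-values do not measure the spread within A375 alone. The filter of this fit counts all 27 libraries together, and only 10581 genes passed it in each line's own fit. A gene expressed in only some lines can be called because no change is measurable in the others. Line and the handling of each line's samples cannot be told apart.

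The authors' deposited table for A2058 called 5118 genes, that for A375 4402, that for SKMEL2 5963 and that over all lines 7218. In genes tested in both, calls of the same sign in the authors' deposited table and in the limma fit numbered 3963, 3740, 4418 and 5951, and calls of opposite sign 0, 0, 0 and 1. Log2 changes correlated with those in the authors' deposited table at r = 0.958, 0.966, 0.958 and 0.906 across genes. For SIRT5 the authors' deposited table gives log2 changes of -2.81, -3.69, -2.92 and -3.10, further from 0 than on the log2(FPKM + 0.5) scale. For MITF the authors' deposited table gives -1.23, -1.11, -1.23 and -1.19. For MYC the authors' deposited table gives -0.56, -0.84, -0.74 and -0.70, and the change in A2058 did not pass there (adjusted p = 0.053).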

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

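Among the tests in this part, those of 3' UTR matches as a contribution and among shared increases and decreases, of the SIRT5 left in KD2, of hairpin differences with the trend with transcript length and GC content removed, of an interferon response in the control arm, of transcript length and GC content along the A375 axis and of sequencing depth were chosen only after the result was seen.

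The knockdown effect differed between lines for 9881 genes by the F-test, led by A2M (adjusted p = 4.5e-15), CD55 (9.8e-13), GPAT3 (1.3e-12), EDNRB (2.2e-12), TIMP1 (5.8e-12) and TGFBR2 (6.1e-12). That test gives each gene 1 variance for all lines, though A375 libraries varied more within arms. It also includes genes that did not pass the filter in every line. Of the 32 gene lists, 19 differed between at least 1 pair of lines with camera, among them the interferon list, lower in A375 than in A2058 (median difference -1.19), and pigmentation, lower in SKMEL2 than in A375 (-0.82). With an estimated correlation 0 of these list differences passed, the lowest adjusted p being 0.060, for MAPK output in SKMEL2 against A2058. The 2 hairpins differed from each other for 9249 genes in A2058, 4811 in A375 and 9522 in SKMEL2, and 7 lists differed between them over the lines. Higher in KD2 were the G2/M, histone and cytosolic ribosome lists. Lower in KD2 were the cholesterol synthesis, citric acid cycle, NF-kB and cytokine, and MAPK output lists. Of these 7 lists 0 passed with an estimated correlation (adjusted p = 0.36 in each). Under quantile normalization 2 of them lost their calls but kept their direction. The median of cholesterol synthesis went from -0.29 to -0.22 and that of MAPK output from -0.35 to -0.24 (camera adjusted p = 0.11 and 0.073).

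Libraries were regrouped at random within each line 100 times, the real grouping included. Only 1 of 100 groupings reached the real count of genes changed over the 3 lines (10354, highest other 1499). The same was true of genes changed the same way in all lines (2250, highest other 0) and of those differing between lines (9881, highest other 5813). A random mix of libraries is therefore excluded as the source of these counts. The same holds for A375 (6054, highest other 3044, and 2807 with both hairpins, highest other 1594) and SKMEL2 (9070, highest other 5622, and 4639 with both hairpins, highest other 3897), each with 1 of 100. In A2058 2 of 100 reached the counts of 8873 and 4736, and the other grouping gave more, 9280 and 5587. It kept the arms whole and set KD1 in the place of the control. Groupings that mix libraries of different arms widen the spread within groups. The lower counts of such groupings show that the arms differ, not that the control is the odd arm. The 1 of 100 in A375 and SKMEL2 therefore does not set the control apart from the other arms either. The 13 gene lists called over the lines were reached by 6 of 100 groupings, with 15 as the highest other, so chance cannot be excluded for that number. Between hairpins there are only 10 splits of 6 libraries, too few for a share under 0.05. The real counts of 9249, 4811 and 9522 compare with highest others of 1, 0 and 0, and 1 of 10 splits reached each.

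The hairpin arms differed for many genes, often in the same direction in all lines. More SIRT5 left by KD2 was not the whole cause, since at least 13.1% of the genes called with both hairpins moved in opposite directions in each line, and neither were trends with transcript length and GC content, since at least 93.0% of the calls between hairpins kept sign and significance once they were removed. A candidate explanation is that each hairpin lowers unintended transcripts through short matches in 3' UTRs: 7-mers chosen for an arm in 2 lines (GAAGAGC for NT, AACCAGA for KD1, CAGCTCC for KD2) went with lower expression in that arm of the left-out line, in other genes, in 9 of 9 tests (t from -6.69 to -13.3, effects from -0.15 to -0.30), though over all genes other 7-mers went with higher expression at a t of up to 9.43. In genes not used to choose the sequences, those rising with each hairpin in all lines carried the control's 7-mer 1.83 times as often as others (44 of 226, Fisher's exact unadjusted p = 0.00012), and those falling carried KD1's 1.66 times (31 of 145, p = 0.0055) and KD2's 1.68 times as often (41 of 145, p = 0.00071), so part of the shared increases and of the shared decreases may be effects of the hairpins' own sequences. Matches to these 3 sequences were not the whole cause. Of genes with none of them, 74.8% in A2058, 35.3% in A375 and 71.5% in SKMEL2 were called between hairpins. For genes with a match the shares were 77.1%, 42.9% and 74.2%. What lies behind the rest stays open.

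Interferon-induced genes were lower in both knockdown arms of all 3 lines. Scaling of the libraries is not the cause, since the list's median was -1.07 or lower under quantile normalization and median-ratio scaling. Direct matches to AACCAGA and CAGCTCC do not account for the fall of the list either. Of the 28 measured members, all with a 3' UTR searched, 0% carried both and 23 members carried neither. Other 7-mers, and effects of the hairpins through a regulator of these genes, were not tested. What stays open is whether SIRT5 loss lowers these genes or the control hairpin raised them: KD1 and KD2 lay together (median difference -0.0305), while the mean log2 level of the list varied among control libraries, from 3.02 to 3.80 in A375 and from 1.93 to 3.03 in SKMEL2, with no untransduced cells here to set the baseline. These 2 cannot be told apart, because every control library carries the same hairpin.

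Within arms, the A375 libraries varied along 1 axis that held 58.1% of the residual variance, against 20.3% in A2058 and 23.3% in SKMEL2, with KD2 replicate 3 at 41.1 and KD2 replicate 1 at -27.5. Transcript length and GC content accounted for 52.2% of the variance of its gene loadings (correlation with GC content -0.69 over 12607 genes), consistent with a difference in library preparation or RNA quality between wells. Depth did not order the libraries, in 0 of 3 arms, and the control library with the truncated raw file was not the source, since the axis kept 107% of its share without it. No biological explanation was tested. With the trend removed, 7255 in place of 6054 genes were called in A375.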

How the results depend on the processing

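Limma-voom on recovered reads, each hairpin tested alone and removal of the trend with transcript length and GC content were chosen after seeing the data. The other alternatives were planned. Counts that stayed within 1.5 times and SIRT5 changes that kept sign and call did so under both other pseudocounts, without a filter, under quantile and median-ratio scaling, in limma-voom and with the trend removed. Requiring an FPKM of at least 5 tests fewer genes and gave 6133 between hairpins in A2058, 5461 changed, 2881 with both hairpins and 5686 between hairpins in SKMEL2, 6852 over the lines and 1487 shared by the lines, while SIRT5 itself dropped out and has no value. Sample weights, whose estimation stopped before its tolerance, gave 4936 with both hairpins in A375. Treating both knockdown arms as 1 group, which adds their difference to the spread, gave 4055, 3157 and 4112 changed genes in A2058, A375 and SKMEL2. The fit over all 27 libraries, with 1 variance per gene for all lines, gave 9378 in A375, where the cause was not tested. At 2 times or more the counts were 895, 1111, 481 and over the lines 301. The authors' deposited tables, which hold more genes (22229 for A2058 and 24259 for SKMEL2), gave 5118 in A2058 and 5963 in SKMEL2. In genes present in both, 4909 and 4647 were called in the limma fit only. The cause was not tested. In all 6 contrasts of hairpin and line 710 genes passed. Of the gene lists 0 passed camera with an estimated correlation (5 at an unadjusted p under 0.05) and 27 passed fry. Leaving out each library in turn gave 8208 to 8773 changed genes in A2058, 4111 to 7804 in A375 and 8167 to 8948 in SKMEL2, and with both hairpins 4336 to 4648, 1665 to 4143 and 4154 to 4516. Between hairpins it gave 8736 to 9269, 3626 to 6493 and 8853 to 9481, and SIRT5 kept its call, at -1.81 to -1.65 in A2058 and -1.58 to -1.49 in A375. Over the lines it gave 9879 to 11128 changed, 1723 to 2506 shared and 8921 to 11535 differing genes, and 12 to 14 lists. In A375 the lowest counts changed and with both hairpins came without control replicate 2, the library with the truncated raw file, and the highest without KD2 replicate 3. The replicate numbers did not pair the libraries: deviations of equal numbers correlated from -0.07 to 0.06 in A2058, -0.62 to 0.43 in A375 and -0.06 to 0.06 in SKMEL2, and 5, 1 and 3 of 9 libraries matched their own number best. With the replicate number as a block 8711, 4958 and 9028 genes changed, 4610, 1977 and 4615 with both hairpins and 9878 over the lines, and no call of a named gene was lost. Of 206 results on named genes under 6524 alternatives, 6519 kept direction and call, 4 lost the call and 1 reversed: MT-ND5 over the lines went from 0.18 to -0.12 under quantile normalization, and the cause was not tested. MT-CO2 and MT-CO3 lost their calls without a filter, and KRT8 without A375 control replicate 2 or SKMEL2 control replicate 3. In simulations with the same dispersion for all lines, 74.6% of changes of 1.5 times were recovered in A375, against 95.5% in A2058 and SKMEL2. These simulations leave out the wider spread among the real A375 libraries. Without KD2 replicate 3 the A375 fit called 7804 genes in place of 6054, so depth is not the only limit there.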

Other observations

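The test of the position of the KD2 sequences and the removal of the trend with transcript length and GC content were the tests in this part chosen only after the result was seen. The gene lists on energy metabolism in this paragraph were not called over the 3 lines, though some of this depended on scaling. Of 67 nuclear genes of oxidative phosphorylation 26 rose, 12 fell and 29 did not pass (26 and 12 also adjusted over the list alone), and COX7C stood far from the rest at 2.14, with NDUFA2 at 0.67 (camera adjusted p = 0.21). The citric acid cycle list had 10 genes up, 10 down and 3 not passed of 23 (11 and 11 adjusted over the list alone), with SUCLG2 at -0.73 and PC at 0.69. Its median was 0.05 while its mean was -0.04 and the test pointed down (camera adjusted p = 0.72). Between the hairpins, however, the citric acid cycle list was lower in KD2 than in KD1 over the lines (median -0.26, camera adjusted p = 0.0058, adjusted p = 0.36 with an estimated correlation). Fatty acid oxidation had 10 up, 6 down and 3 not passed of 19 (10 and 7 adjusted over the list alone), with ACADM at -0.81 and SLC25A20 at 0.76 (camera adjusted p = 0.55). Glycolysis had 3 up, 12 down and 7 not passed of 22 (3 and 12), with ALDOC at -0.89 and the lactate transporter SLC16A3 at 0.59 (camera adjusted p = 0.17). Of 15 genes of glutamine metabolism and the urea cycle 2 rose, 7 fell and 6 did not pass (2 and 7), with ARG2 at 0.90 and PYCR1 at -0.69 (camera adjusted p = 0.18). The 13 genes of the mitochondrial genome had 4 up, 2 down and 7 not passed (4 and 1), with MT-ND6 at 0.30 (camera adjusted p = 0.55). They went in different directions in the lines, 11 rising in A2058 and 12 falling in SKMEL2 (camera adjusted p = 0.0093 and 0.0043, and adjusted p = 0.65 and 0.58 with an estimated correlation). In the fit over all libraries both calls were lost under quantile normalization (medians 0.08 and -0.04, camera adjusted p = 0.40 and 0.99). With the trend with transcript length and GC content removed, that in A2058 missed the threshold with a similar median (0.21 to 0.19, camera adjusted p = 0.16). Under quantile normalization glycolysis and glutamine metabolism were called as falling over the lines (medians -0.20 and -0.19, camera adjusted p = 0.0016 and 0.038), while oxidative phosphorylation and the mitochondrial genome turned to medians of -0.05 each and were not called (adjusted p = 0.29 and 0.54). Cholesterol synthesis had 6 up, 10 down and 8 not passed of 24 (6 and 10), with SQLE at -0.55 (camera adjusted p = 0.28). The hypoxia list had 5 up, 11 down and 3 not passed of 19 (5 and 11), with CA9 at -1.94 (camera adjusted p = 0.078).

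Lineage, signalling and stress lists were mixed as well. Of 16 neural crest genes 5 rose, 9 fell and 2 did not pass (5 and 9 adjusted over the list alone), with SNAI2 at -1.14, FOXD3 at -0.84 and S100B at 0.80 (camera adjusted p = 0.23). The invasive, dedifferentiated list had 9 up, 9 down and 4 not passed of 22 (9 and 9), with NT5E at 1.66 and CCN2 at -0.81. Its median was -0.01, its mean 0.08 and its test pointed up (camera adjusted p = 0.77). MAPK output genes had 7 up, 8 down and 1 not passed of 16 (7 and 8), with DUSP5 at 2.08, SPRY4 at 1.13, EGR1 at -1.40 and CCND1 at -0.79, and a median of -0.08 beside a mean of 0.05 (camera adjusted p = 0.81). In the fit over all libraries the neural crest and MAPK output lists fell in SKMEL2 (median -0.35 each, camera adjusted p = 0.0010 and 0.014). Neither was called in A2058 or A375. Both were lower in SKMEL2 than in A2058 (camera adjusted p = 0.0063 and 5.2e-08, and adjusted p = 0.11 and 0.060 with an estimated correlation). Of 19 NF-kB and cytokine genes 12 rose, 5 fell and 2 did not pass (12 and 5), with IL1B at 1.19 and PTGS2 at -0.85 (camera adjusted p = 0.19). This list was lower in KD2 than in KD1 over the lines (median -0.47, camera adjusted p = 0.012, adjusted p = 0.36 with an estimated correlation). Extracellular matrix genes had 6 up, 8 down and 7 not passed of 21 (6 and 8), with ITGB3 at 1.29 and MMP2 at -0.93 (camera adjusted p = 0.72). The ER stress list had 7 up, 4 down and 8 not passed of 19 (7 and 4), with HYOU1 at -0.72 (camera adjusted p = 0.55). Genes of protein acetylation and chromatin had 8 up, 11 down and 5 not passed of 24 (9 and 11), with HDAC5 at 0.62 and KAT6A at -0.58 (camera adjusted p = 0.55). The cytosolic ribosome list had 40 up, 11 down and 24 not passed of 75 (40 and 11), with RPL14 at -0.90 and RPL11 at 0.59 (camera adjusted p = 0.061). Its median turned from 0.13 to -0.04 under quantile normalization, where the list was called as falling (camera adjusted p = 0.042), and in A375 fell from 0.65 to 0.20. The 7 sirtuins had 3 up, 3 down and 1 not passed (3 and 4; camera adjusted p = 0.55).

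Markers of other cell types were compared where they were measured. Of 6 measured epithelial markers 2 rose, 3 fell and 1 did not pass (2 and 3 adjusted over the list alone), with CDH1 at -0.59 and KRT18 at 0.55 (camera adjusted p = 0.55). Of 4 fibroblast markers 0 rose and 1, FAP, fell at -0.29 (0 and 1; camera adjusted p = 0.49). With the estimated correlation 0 of the lists in these 3 paragraphs passed over the 3 lines. Immune and endothelial markers had 1 measured gene each and were not tested. CD14 was at 0.68 (adjusted p = 9.4e-08) and KDR at -0.01 (adjusted p = 0.92). The highest FPKM of any immune marker in any library was 3.75 in the controls, 6.46 in KD1 and 12.4 in KD2, of any endothelial marker 3.60 and of any epithelial marker 136.

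The 7-mers that went with low expression in the knockdown arms can be set against the SIRT5 transcript, which is 4564 nucleotides long in 10 exons and holds 23.0% of all 7-mers, or 39.2% with either strand. AACCAGA of KD1 lies at nucleotides 417 to 423, in the coding part of exon 3 (chromosome 6, 13584189 to 13584195), with its reverse complement in the 3' UTR. For KD2, TAGTGCA, the leading 7-mer unrelated to CAGCTCC at rank 4, lies at 521 to 527 in the coding part of exon 4, and the reverse complement of CAGCTCC at 510 to 516 of the same exon (chromosome 6, 13588387 to 13588404). That reverse complement also lies at 552 to 558 and, in the 3' UTR, at 4152 to 4158. TAGTGCA and the nearest site fall in a stretch of 18 nucleotides on opposite strands, as 0.089% of 100000 random pairs of 7-mers did within 21 nucleotides. This is consistent with both strands of the KD2 hairpin acting on other transcripts, a hypothesis found and tested on the same data. GAAGAGC of the control also occurs in the SIRT5 3' UTR. Over all permuted gene labels the lowest t of any 7-mer was -4.81, against -12.1 for GAAGAGC, -12.5 for AACCAGA and -18.0 for CAGCTCC. In the other direction the highest t was 9.43 for the control, 7.54 for KD1 and 6.68 for KD2, so the permuted labels understate the background.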
